A study of Mus musculus with 8 samples.

How the data were processed

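The series measured ribosome footprints and polyA-selected mRNA in forebrains of mouse embryos at embryonic day 14.5. Ribosome footprints (RPF) are the short mRNA fragments that a ribosome protects from RNase digestion, so their number per transcript reflects how many ribosomes were translating it. The 8 libraries fall into 4 groups of 2: wild-type (WT) and Elp3 conditional knockout (Elp3cKO) forebrains, each assayed for footprints and for mRNA. Groups and replicate numbers were taken from the sample titles. The labels do not say whether replicates came from separate embryos, so the p-values measure only the spread between these libraries, which may be technical. They give no sequencing batch.

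Per the labels' protocols, footprints of 28 to 32 nt from the monosome fractions of sucrose gradients were gel-purified, ligated to a linker with random bases, and amplified by PCR, while mRNA libraries were made with a TruSeq kit. The deposited values are raw read counts per UCSC known gene ID, 1 table per assay, per the file headers. The submitters' processing notes name CASAVA 1.8, Bowtie 1.0.0 and the mm10 build. The counting tool, the part of each transcript that was counted, any use of strand, and any removal of PCR copies are not given in the sources used here. Reads shared between overlapping or near-identical genes are therefore uncertain for every transcript. The footprint table lists 16177 IDs, of which 1358 have no count in any library. The mRNA table lists 14989 IDs, each with at least 1 count. The tables share 14801 IDs.

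Both tables give IDs without gene symbols. None of the 16365 IDs of the 2 tables matched the gene name tables used here (0 matches), so gene names and genomic positions are not used here. For the same reason the level of Elp3 itself, which would check the genotype labels, was not examined, and 26 gene lists fixed before the data were examined (Elongator, ATF4 targets, endoplasmic reticulum chaperones, progenitor and neuron markers, markers of other cell types and others) were not tested. The rule fixed before the data were examined would name, for each comparison, Elp3, up to 10 transcripts with the smallest p-values in each direction, and list members. Because IDs without names say little, only 4 IDs are printed, chosen after their values were seen: 2 that rose (the smallest p-value, and the largest fold change among those called) and the 2 that passed the test of translational efficiency.

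Counts were analysed in R 4.3.3 with edgeR 4.0.16. Transcripts were kept with filterByExpr (minimum count 10), libraries were scaled by TMM within each assay, and Elp3cKO was compared with WT by the quasi-likelihood test, separately for footprints (12691 transcripts tested) and mRNA (11697). A change in translational efficiency, the footprint level relative to the mRNA level, was tested as the interaction of genotype and assay in 1 model over all 8 libraries, for the 11588 transcripts kept in both assays. P-values were adjusted by the Benjamini-Hochberg method over all transcripts of a comparison, and an adjusted p under 0.05 was called. Standard errors (SE) of log2 fold changes were taken as the fold change over the root of the F statistic. Levels are given as CPM (counts per 1000000 counts of the TMM-scaled library), as mean ± SD of 2 libraries. With 2 libraries per group, single values were not tested by permutation.

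Total counts were between 4119478 and 10082980 in the footprint libraries and between 2059059 and 4823834 in the mRNA libraries. A count of 0 allows up to 3 counts, which is 0.298 to 0.728 CPM for footprints and 0.622 to 1.46 CPM for mRNA. These limits and the exact 95% intervals of count ratios cover counting error only, since PCR copies are not independent molecules. Libraries of 1 group differed by more than sampling noise: the chi-square statistic per degree of freedom was 14.5 for WT and 6.78 for Elp3cKO footprints, and 3.88 for WT and 2.98 for Elp3cKO mRNA. Between the genotypes it was 11.5 and 11.3 for WT footprint replicate 1 and 23.5 and 18.3 for WT footprint replicate 2 (against Elp3cKO replicates 1 and 2), and 4.19 to 8.13 for mRNA. This statistic grows with the counts of the libraries compared, so its values do not rank pairs of unequal depth. The spread of each library was described by the variance-to-mean ratio: the mean squared difference between its count and the count expected from the other libraries of its assay, divided by the expected count. Poisson counting noise of the library alone gives a ratio of 1. Noise of the other libraries and differences between the genotypes add to the ratio.

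The tests were tried on simulated counts with the real means and totals, in 5 simulations with 200 changed transcripts each. The simulated variance added the mean times the library's variance-to-mean ratio (after allowing for the noise of the other libraries) and a dispersion term that grows with the squared mean. The dispersion was the median that edgeR fitted to abundant transcripts. Part of the real spread may be counted in both terms, so the shares called may be too low. The footprint test, run on 12691 transcripts, called 9.25% of 1.5-fold, 37.9% of 2-fold and 73.9% of 4-fold changes, and the mRNA test, run on 11697, called 17.6%, 48.4% and 85.8%. The interaction test, run on 11588 transcripts with only footprints changed, called 0.896% of 1.5-fold, 15.5% of 2-fold and 62.4% of 4-fold changes. Among unchanged transcripts, 0.0464% (footprints), 0.0296% (mRNA) and 0.0105% (interaction) were called.

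Alternatives set before the data were examined were DESeq2 (1.42.0) size factors and upper-quartile factors in edgeR, no filter beyond 1 count, a mean of at least 50 counts, the DESeq2 Wald test, limma (3.58.1) voom, a replicate block, a fit on all 8 libraries, 2 other models of translational efficiency, and leaving out each library. A weight per library in limma voom was added after seeing the data.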

Results

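The study profiled translation and transcript levels in the forebrain of E14.5 mouse embryos labelled WT or Elp3 conditional knockout (Elp3cKO). Elp3 is the catalytic subunit of Elongator, a complex that modifies wobble uridines of tRNAs. The questions that follow from the design are which transcripts changed in ribosome footprints and in mRNA between the genotypes, and whether footprints changed beyond the change of the mRNA. Each of the 4 groups (2 genotypes in 2 assays) held 2 libraries. The WT footprint libraries had total counts of 9146852 (replicate 1) and 10082980 (replicate 2), and the Elp3cKO footprint libraries 8430954 and 4119478. The WT mRNA libraries had 4297830 and 2998847, and the Elp3cKO mRNA libraries 2059059 and 4823834. The most abundant transcript took between 0.895% and 1.07% of any library.

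Footprint libraries varied more than mRNA libraries. The biological coefficient of variation fitted by edgeR was 23.7% for footprints and 11.7% for mRNA. WT footprint replicate 2, the most deeply sequenced library, had the highest spread. For transcripts with an expected count of 10 to 20, its variance-to-mean ratio was 20.1 ± 2.27 (SE over 751 transcripts), against 8.32 ± 0.539 in WT replicate 1, 9.42 ± 0.613 in Elp3cKO replicate 1 and 10.4 ± 0.823 in Elp3cKO replicate 2. In this range 206 of the 751 transcripts (27.4%) had a count of 0 in WT replicate 2, where Poisson counting would give 0.000583%. The corresponding shares at 0 were 7.05%, 3.92% and 4.40% in the other footprint libraries, in the same order. In the mRNA libraries the ratios in this range were between 2.77 and 5.33. Over all tested transcripts, libraries of 1 genotype were not always the closest in either assay. Log2 CPM of WT footprint replicate 1 had Pearson's r = 0.943 with WT replicate 2, 0.968 with Elp3cKO replicate 1 and 0.935 with Elp3cKO replicate 2 (across transcripts), and log2 CPM of WT mRNA replicate 1 had r = 0.967, 0.961 and 0.968 in the same order.

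**Figure D1:**
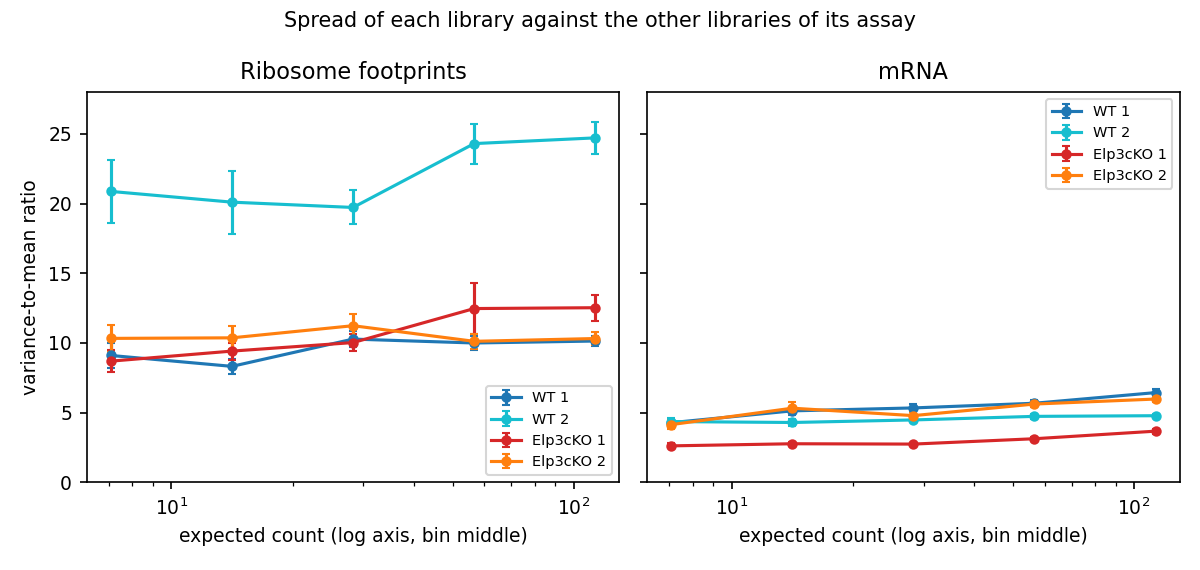
Variance-to-mean ratio (y axis) of each library against the other libraries of its assay, by expected count (log x axis, bins from 5 to 160), for footprints (left) and mRNA (right); bars are SE over transcripts, and 1 and 2 are replicate numbers. WT footprint replicate 2 lies between 19.7 and 24.7 in every bin, above the other footprint libraries, which lie between 8.32 and 12.5.

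The first comparison asked which transcripts carried more or fewer ribosome footprints in Elp3cKO forebrains. Footprints of 51 transcripts rose and those of 69 fell, together 0.946% of the 12691 tested (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The median log2 fold change was 0.93 among those that rose, 23 of which rose over 2-fold, and -0.78 among those that fell, 20 of which fell over 2-fold. The smallest p-value among the rises belonged to uc009axf.1, whose footprints went from 64.9 ± 1.41 CPM in WT to 311 ± 34.8 CPM in Elp3cKO (SD, n = 2), a log2 fold change of 2.26 (SE 0.14, edgeR adjusted p = 2.81e-07). The largest fold change among the called transcripts was that of uc009twt.1, which had 10 and 0 footprint counts in WT replicates 1 and 2 and 382 and 162 in the Elp3cKO libraries. Its pooled count ratio was 83.4 (exact 95% interval 45.0 to 175), but the size rests on single WT libraries. It was 39.6 (21.4 to 83.1) without WT replicate 2, and 146 without WT replicate 1, with the WT count of 0 set to 3. The value of 146 is not a lower bound, because 27.4% of transcripts expected at 10 to 20 counts were at 0 in WT replicate 2. The adjusted p of uc009twt.1 was 5.65e-05 with edgeR but 0.082 with limma voom and 0.106 with library weights added. The footprints of uc007ujl.2 fell from 143 ± 29.9 to 29.9 ± 4.05 CPM (log2 fold change -2.27, SE 0.20, edgeR adjusted p = 2.6e-05), and those of uc007cyn.1 from 179 ± 13.9 to 80.0 ± 7.92 CPM (log2 fold change -1.17, SE 0.15, edgeR adjusted p = 0.000765).

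The counts of footprint changes depended on single libraries. With WT footprint replicate 2 left out, 82 transcripts rose and 65 fell, and 51 of the 51 rises and 46 of the 69 falls of the full set were called again. With WT replicate 1 left out, so that replicate 2 alone stood for WT, 494 rose and 447 fell, and without Elp3cKO replicate 1 or replicate 2 the numbers were 26 and 7, and 22 and 12. The DESeq2 Wald test called 105 rises and 142 falls, of which 38 and 62 were shared with edgeR.

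The second comparison asked which mRNAs changed in level. Of the 11697 transcripts tested, 107 rose and 118 fell in Elp3cKO, 1.92% in all (edgeR quasi-likelihood test, adjusted p under 0.05). The median log2 fold change was 0.70 among the rises and -0.67 among the falls, and 34 rises and 25 falls exceeded 2-fold. The counts depended on the model, since the fit on all 8 libraries called 57 rises and 30 falls. The transcript uc009axf.1 again had the smallest p-value among the rises, going from 42.2 ± 1.48 to 142 ± 14.8 CPM (SD, n = 2; log2 fold change 1.73, SE 0.16, edgeR adjusted p = 2.64e-08). The largest change among the called transcripts was again that of uc009twt.1, with 1 count in each WT library against 43 and 63 in the Elp3cKO libraries, a pooled count ratio of 56.2 (exact 95% interval 15.2 to 470, edgeR adjusted p = 3.21e-06). The mRNA of uc007ujl.2 was at 116 ± 16.9 CPM in WT and 127 ± 9.96 in Elp3cKO (log2 fold change 0.13, SE 0.14, edgeR adjusted p = 0.776), and that of uc007cyn.1 at 294 ± 7.09 and 293 ± 19.3 CPM (SE of the log2 fold change 0.11, edgeR adjusted p = 0.997). The mRNA counts moved less with single libraries than the footprint counts did: 61 rose and 54 fell without WT replicate 1, and 45 rose and 43 fell without Elp3cKO replicate 2.

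Footprint and mRNA changes were then set side by side for the 11588 transcripts tested in both assays. The labels do not say whether the footprint and mRNA libraries were made from the same embryos. If they were, differences between embryos could add to the agreement between the assays, apart from any effect of the genotype, and the overlap below does not tell these apart. Shared embryo differences would also make the replicate 1 minus 2 differences of the assays correlate, with a sign set by the numbering. Over these transcripts, that correlation was -0.021 for WT and 0.022 for Elp3cKO, against r = 0.30 for the genotype changes. This argues against embryo differences as the main source of the agreement over all transcripts. It does not cover the called transcripts alone, or what both libraries of a genotype share. Transcripts called in both assays numbered 64, and all 64 changed in the same direction. These were 35 of the 51 footprint rises and 29 of the 68 footprint falls tested in both, where independent lists would share 0.471 and 0.692 (one-sided Fisher's exact test over transcripts, p = 7.89e-62 and 4.2e-41; transcripts are not independent replicates). Among transcripts called in footprints, 49 of 51 rises and 67 of 68 falls had the same sign in mRNA, and among those called in mRNA, 98 of 107 rises and 116 of 118 falls had the same sign in footprints. Over all 11588 transcripts, called or not, 61.1% had the same sign in both assays. The 35 shared rises had a median log2 fold change of 0.93 in footprints and 1.01 in mRNA, and the 29 shared falls -0.88 and -0.71. Footprint changes alone passed the test in 55 transcripts and mRNA changes alone in 161, which does not show that the assays differed there. Without WT footprint replicate 2, 36 rises and 23 falls were shared, 1 transcript was called in opposite directions, and 132 of 143 footprint calls had the same sign in mRNA.

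Over all 11588 transcripts the log2 fold changes of the assays had Pearson's r = 0.30 and Spearman's rho = 0.29 across transcripts, given without a p-value because transcripts are not independent replicates. The correlation grew with footprint abundance, with r = 0.24, 0.36, 0.41 and 0.55 from the least to the most abundant of 4 equal groups of transcripts. Leaving out 1 library gave r between 0.16 (without Elp3cKO mRNA replicate 2) and 0.33.

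**Figure D2:**
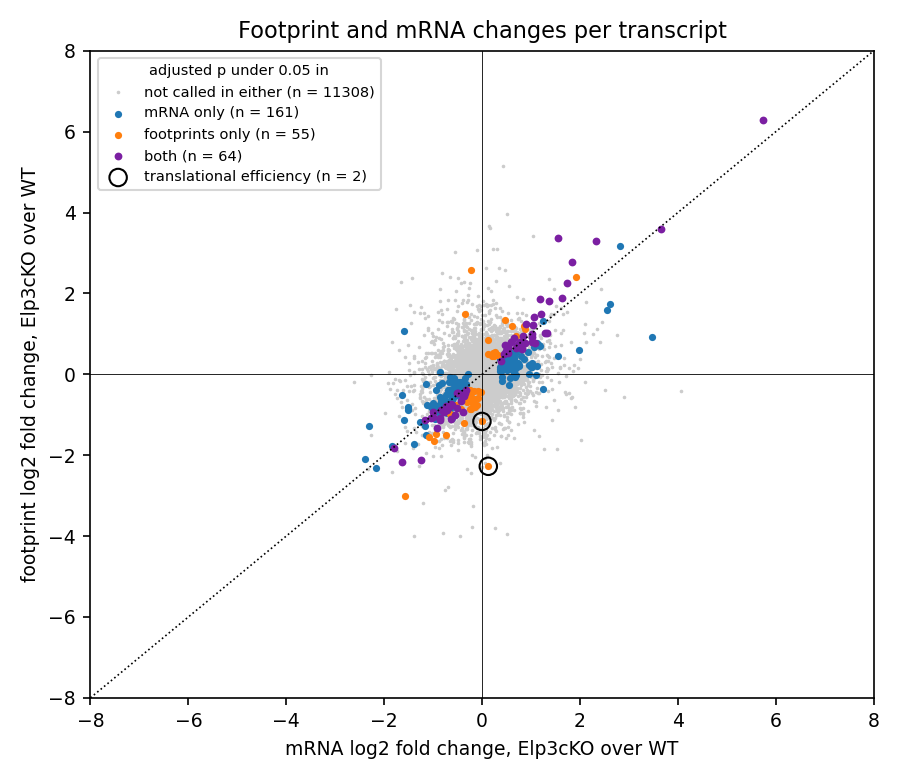
Log2 fold change of Elp3cKO over WT in mRNA (x axis) and footprints (y axis), 1 point per transcript tested in both assays, coloured by the assay in which it passed an adjusted p of 0.05; the dotted line marks equal change. The 64 transcripts called in both assays lie in the upper right (35) and lower left (29), and the 2 circled transcripts that passed the test of translational efficiency lie at an mRNA change near 0.

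The third comparison asked whether footprints changed relative to mRNA. Translational efficiency fell in 2 transcripts and rose in 0 of 11588 (edgeR quasi-likelihood test of the interaction, adjusted p under 0.05). Because each assay was scaled on its own, these are changes relative to most other transcripts. A rise or fall of translation common to all transcripts would not be seen. At an unadjusted p under 0.05 there were 272 rises and 339 falls, together 5.27% of the transcripts tested, where chance gives 579 transcripts. The DESeq2 Wald test called 3 falls and 0 rises, and limma voom 2 and 0. The efficiency of uc007ujl.2 fell by 2.40 on the log2 scale (SE 0.25, edgeR adjusted p = 4.18e-05), to 0.189 of its WT value, and that of uc007cyn.1 had a log2 fold change of -1.16 (SE 0.17, edgeR adjusted p = 0.00597), to 0.448 of its WT value. For both, the footprint counts fell while the mRNA levels differed by less than their standard errors. The fall of uc007ujl.2 was called in all 8 fits that left out 1 library (adjusted p from 1.95e-06 to 0.00469). That of uc007cyn.1 was called in 4 of the 8: without Elp3cKO footprint replicate 1, WT mRNA replicate 1, WT mRNA replicate 2 or Elp3cKO mRNA replicate 2 its adjusted p was 0.15, 0.0875, 0.133 and 0.146, with log2 fold changes of -1.05, -1.18, -1.14 and -1.09. With WT footprint replicate 2 standing alone for WT (replicate 1 left out), 34 transcripts rose and 10 fell, against 1 and 3 when replicate 2 was the one left out.

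**Figure D3:**
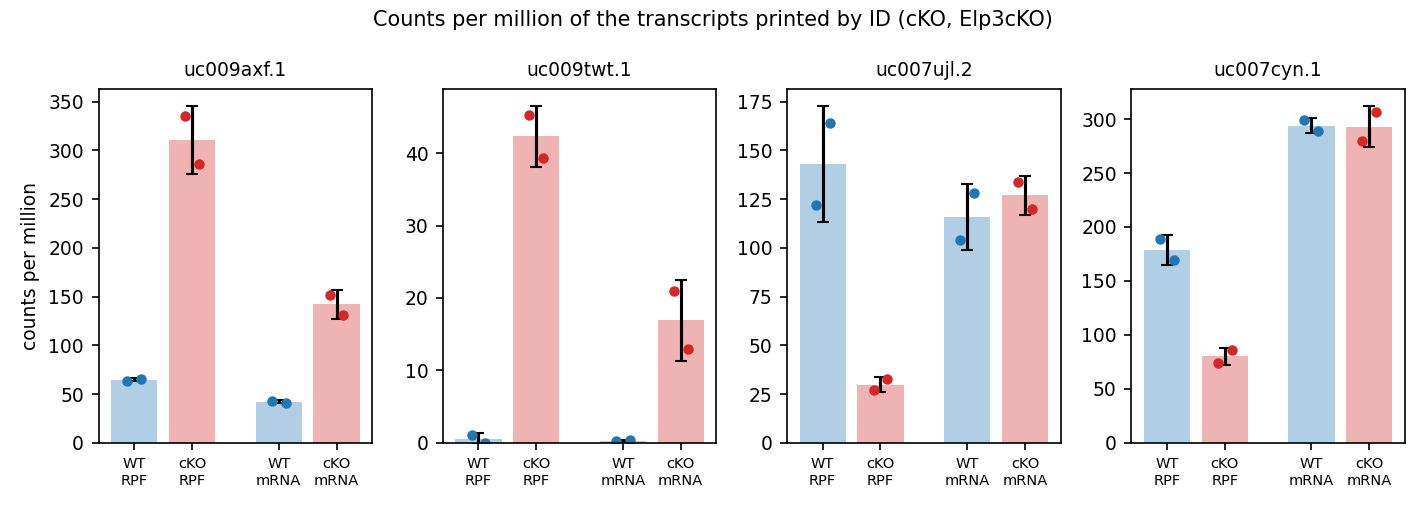
CPM (y axis, from 0) of the 4 transcripts given by ID in footprints (RPF) and mRNA of WT and Elp3cKO (cKO) forebrains; points are libraries, bars group means, and error bars SD of 2 libraries. Footprints and mRNA both rise for uc009axf.1 and uc009twt.1, while for uc007ujl.2 and uc007cyn.1 footprints fall from 143 to 29.9 and from 179 to 80.0 CPM with mRNA at similar levels.

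The median SE of a log2 fold change was 0.28 for footprints, 0.23 for mRNA and 0.35 for translational efficiency. In the simulations 15.5% of 2-fold changes of efficiency were called, a share that may be too low.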

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

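Of the tests reported here, those on the mRNA fall, on the fold change of uc007cyn.1 in fits without 1 library and on other splits of the libraries were chosen after the result was seen. The 2 results here stood out because the genotype effect differed between the assays by a test of that difference: the log2 fold change of footprints minus that of mRNA was -2.4 for uc007ujl.2 and -1.16 for uc007cyn.1. In these libraries the mRNA did not fall along with the footprints: the mRNA log2 fold change less 2 standard errors came to at most a share of 0.18 of the footprint log2 fold change. Both transcripts were picked for a difference between the assays, which favours a small share, so this test does not decide on a fall of the mRNA. A single deviating library is argued against for uc007ujl.2, whose adjusted p stayed at or under 0.00469 in the 8 fits that left out 1 library. The same test, set before its result was seen, was not passed by uc007cyn.1, whose adjusted p rose to as much as 0.15 and whose call ended in 4 of the 8 fits. Its log2 fold change stayed at or below -1.05 (SE 0.19) in all 8, against -1.16 (SE 0.17) with every library, which argues against 1 library as the source of the whole fall, but that test replaced the first one afterwards. What stays open is reads shared with an overlapping or similar gene, an altered transcript that keeps its mRNA reads and loses coding sequence, and a change of translation between the genotypes, none of which was tested. The tables pair no ID with a name, so whether either transcript belongs to the targeted gene was not examined.

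With 2 libraries per group there are 3 ways to split the 4 libraries of an assay, too few for a share under 0.05. The real split gave 120 footprint calls and 225 mRNA calls, and the highest of the other splits gave 0 and 1, so in each assay 1 of the 3 splits reached the real count. Each group of the other splits holds 1 WT and 1 Elp3cKO library. Any genotype difference then adds to the spread within groups and lowers the calls. Their low counts therefore do not show how many calls arise without a genotype difference.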

How the results depend on the processing

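Counts of calls are given as rises and falls, with 51 and 69 for footprints, 107 and 118 for mRNA, and 0 and 2 for translational efficiency as reported. Scaling by DESeq2 size factors or upper-quartile factors and a mean of at least 50 counts left all 6 counts within 1.5 times these values, and no scaling moved the median change of all transcripts by 0.1. Each of these scalings sets the change of most transcripts near 0, so this median cannot show a shift common to all transcripts. Footprint counts were 177 and 198 with no filter beyond 1 count, 105 and 142 with the DESeq2 Wald test, 100 and 141 in the fit on all 8 libraries, and 137 and 164 with a weight per library in limma voom, which was chosen after seeing the data. The mRNA counts were 57 and 30 in the fit on all 8 libraries, and 179 falls with limma voom and 178 with library weights. Efficiency counts were 1 and 4 when the separate fits were subtracted. The cause of these moves was not tested. Leaving out 1 library gave 22 to 494 and 7 to 447 for footprints, 45 to 158 and 43 to 143 for mRNA, and 0 to 34 and 1 to 10 for efficiency. With 1 library left in a group, that library is assumed to vary like the others, which WT footprint replicate 2 (the case with 494 and 447) did not. The correlation of footprint and mRNA changes was 0.42 (Pearson) and 0.37 (Spearman) at a mean of at least 50 counts, and 0.16 to 0.33 and 0.19 to 0.32 with 1 library left out. No direction reversed for the 4 transcripts given by ID where a call was made, and where a test was run, calls ended for uc009twt.1 footprints in 2 limma fits and for the efficiency of uc007cyn.1 in 4 fits without 1 library. For uc009twt.1, DESeq2 gave no adjusted p in either assay, and at a mean of at least 50 counts its mRNA and its efficiency were not tested, because that filter removes its mRNA.

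Libraries with the same replicate number did not deviate together (correlation of replicate 1 minus 2 between genotypes 0.05 for footprints and 0.017 for mRNA, and between assays -0.021 for WT and 0.022 for Elp3cKO), and the labels tie no number to a litter or day, so the numbers were not taken to pair the samples. With the replicate block, footprint counts were 190 and 193, mRNA counts 166 and 210, and efficiency counts 3 and 2. The tests of gene lists and of Elp3 set before the data were examined were not run, for lack of gene names. By total count, depth limits Elp3cKO mRNA replicate 1 most, where 3 counts correspond to 1.46 CPM, and among the footprint libraries Elp3cKO replicate 2, where they correspond to 0.728 CPM.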

Other observations

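The tests on the spread of WT footprint replicate 2 were chosen after the result was seen. The other tests in this part were set before theirs.

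The deepest library was the least even. WT footprint replicate 2 had 3082 IDs at 0 and 97 at a count of 1, against 2256 and 206 in WT replicate 1, 2062 and 267 in Elp3cKO replicate 1, and 3005 and 168 in Elp3cKO replicate 2, whose total count was 4119478. Low depth is argued against by the 10082980 counts of WT replicate 2, the highest total of all. Variation of expression between embryos, as the only source of the spread, would make the variance-to-mean ratio grow with the expected count. The ratio at 80 to 160 expected counts was 1.18 times that at 5 to 10, over a 16-fold range of counts. A part from embryos on top of a level ratio is not excluded. In the other footprint libraries the ratios at 5 to 10 and at 80 to 160 were 9.11 and 10.1 (WT replicate 1), 8.70 and 12.5 (Elp3cKO replicate 1), and 10.3 and 10.3 (Elp3cKO replicate 2). A nearly level ratio therefore does not set WT replicate 2 apart. A level ratio is consistent with reads that are repeated copies of few captured molecules, a hypothesis that the random linker bases could test in the reads, which were not used here. After allowing for the noise of the other libraries, the ratio of WT replicate 2 itself was 17.1, against 4.72 in WT replicate 1, 5.81 in Elp3cKO replicate 1 and 9.45 in Elp3cKO replicate 2. The total divided by this ratio was 589925, against 1939434, 1450853 and 435913 in the same order, so it was lower still in Elp3cKO replicate 2.

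Few transcripts changed in translational efficiency relative to the others, and low power stays open as a reason, since 15.5% of simulated 2-fold changes were called, a share that may be too low. The scaling within each assay removes any change of efficiency common to all transcripts, so the few calls do not bear on one. Whether noise accounts for the modest correlation of footprint and mRNA changes stays open. Over 8572 transcripts with a mean of at least 50 counts in each assay, r was 0.398 as observed. A separate calculation at this minimum, given above, had 0.42. After the replicate variance was subtracted from each assay's variance, r was 0.912 (95% bootstrap interval over transcripts 0.864 to 0.963). This subtraction can only raise r, so the rise itself decides nothing. Footprint changes also seemed larger than mRNA changes: for the 300 transcripts with the largest change in 1 pair of mRNA libraries (averaged over the 4 such pairs), the mean footprint change was 1.25 times (1.10 to 1.42) the mRNA change in the other pair, and with transcripts picked on footprints the mRNA change was 0.797 times (0.679 to 0.920) the footprint change. A prior count of 0.25 in place of 2 also gave 1.25 (1.10 to 1.41), but at these counts it left the mean mRNA change at 0.309 against 0.307 (log2), so it decides nothing about the prior count. Without WT footprint replicate 2 the ratio was 1.07 (0.924 to 1.25), so an artifact of that library stays open. The intervals treat transcripts as independent and leave out differences between embryos.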
